A study of Colocasia esculenta with 9 samples.

How the data were processed

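Leaf RNA of 3 taro cultivars was measured by RNA-seq in 9 libraries, 3 per cultivar. Per the labels' protocols, RNA was extracted with CTAB from 4 g of leaf and dried for 40 h before shipment, and stranded TruSeq libraries were made. Per the submitters' processing notes, bcl2fastq 1.8.4, Trimmomatic 0.33, STAR (given there as version 3.5.0a), featureCounts and Subread 1.4.6 were used. Per the file headers, the deposited counts were made with featureCounts 1.4.6-p4, which counted read pairs as fragments over exons and summed them by gene. The recorded command did not set strand, although the kit keeps it, so RNA of the opposite strand on the exons of a gene model counts for that gene model. It also did not count fragments that mapped to several places or that overlapped more than 1 gene model, so members of near-identical gene families and overlapping genes are undercounted. In the annotation 2060 neighbouring gene models overlap from first to last exon, introns included, all 2060 on opposite strands. The name of the genome build beyond the scaffold names is not given in the sources used here. The counts were used as deposited, with no rounding.

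No gene model has a name or product in the files, so 0 of the 27 gene lists written before the data were examined could be matched, and the set tests planned on them (camera and fry) and the marker lists were not run. Identifiers are gene models and not transcripts, so the planned summing to a parent gene was not needed. The rule for named genes, fixed before the data were examined, took for each comparison the 2 gene models with the largest log2 fold change in each direction among those with an adjusted p under 0.05, a mean of at least 5 CPM over the 9 libraries, and all 3 libraries of 1 cultivar above all 3 of the other. Coordinates are counted from 1, as in the files.

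Cultivar and replicate came from the labels. No pair of libraries of a cultivar agreed within sampling noise in a chi-square test over gene models with at least 20 fragments, so each counted as 1 replicate. Gene models were tested in R 4.3.3 with edgeR 4.0.16, using glmQLFit and glmQLFTest (two-sided) with TMM factors and filterByExpr (minimum count 10, minimum total 15). All 9 libraries entered 1 fit with cultivar as the only term, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The filter kept 18865 gene models. The biological coefficient of variation was 0.44. CPM values use the TMM factors. Approximate standard errors (SE) were taken from the fitted log2 fold change and its F statistic. Where a cultivar had no fragment of a gene model, this SE does not measure how closely the fold is known. A gene model counted as expressed in a cultivar at 1 CPM or more in all 3 libraries and as not detected with 0 fragments in all 3. Folds against such a group are lower bounds, the mean CPM of the higher cultivar over 3 fragments in the TMM-scaled total of the group, and the fitted log2 fold change of such a gene model is no bound. For counts of 1 to 10 fragments the ratio is that of the pooled fragments, with a 95% Poisson interval.

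Similarity was tested with an exact permutation over 280 assignments of Euclidean distances on log2(CPM + 1). Structural classes were tested with Fisher's exact test, with scaffolds of at least 20 tested gene models, and Benjamini-Hochberg adjustment over 89 classes. Neighbouring calls were compared with 10000 shuffles of the calls among tested gene models. The depth ranged from 5468567 to 18175384 fragments per library, and the floor of 3 fragments from 0.1405 to 0.6432 CPM per library. The gene models seen only in a cultivar, the comparison of each library with the others of its cultivar and the members of neighbouring pairs were counted with CPM without TMM factors.

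The fit was tested on simulated data with the means and depths of these libraries, with 100 gene models changed per fold size in each of 5 runs over 18865 gene models. It recovered 41.8% of 4-fold and 85.2% of 16-fold changes between Palau 10 and Niue, 38.8% and 86.6% between Sam-07 and Niue, and 39% and 83% between Sam-07 and Palau 10. The share of false calls was 5.1%, 5.3% and 5.9% in the same order. The simulated gene models varied independently under the model of the fit, whereas gene models of the real libraries can vary together. These shares may therefore not hold for the real data. The alternatives were RLE factors, library size only, DESeq2 1.42.0, no filter, a filter of 10 CPM in 3 libraries, robust estimation, the replicate number as a block, a 2-fold threshold, only the libraries of the pair, other pseudocounts and presence limits, and leaving out each replicate. Only Niue has a replicate 4, so with the block Niue replicate 4 added nothing to the comparisons between cultivars. Thinning to the smallest library and removing the 5 abundant gene models were added after seeing the data.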

Results

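Leaf RNA was sequenced from 3 cultivars of taro (Colocasia esculenta), a clonally propagated aroid grown for its starchy corm and its leaves. The cultivars were Niue, Palau 10 (also called Ngerruuch) and Sam-07 (also called Samasama), with 3 libraries each. The plants were 8 months old, came from tissue culture and grew in a chamber at 27 °C with 85% humidity and a 12 h photoperiod, and RNA came from the 2 youngest leaves. Counts covered 57034 gene models of a taro assembly, of which 27762 had a fragment in some library. The totals assigned to gene models were 15244913, 6083660 and 5468567 fragments for Niue replicates 2, 3 and 4. They were 14857098, 14552704 and 14069579 for Palau 10 replicates 1, 2 and 3, and 11095909, 18175384 and 8513507 for Sam-07 replicates 1, 2 and 3. Not detected means 0 fragments over a cultivar, which allows a level of up to 3 fragments, or 0.1142 CPM (fragments scaled to a common library total of 1e6) in Niue, 0.06512 CPM in Palau 10 and 0.07703 CPM in Sam-07. Intervals and floors cover counting error only. Sequence differences that keep fragments from mapping to the assembly, or fragments that map to several places, can also leave 0 fragments. Not detected therefore does not show that a gene is silent or missing. The labels do not say whether the replicates came from separate plants, so the p-values measure only the spread between these samples, which may be technical. The files pair no gene model with a name or product, and gene models are therefore given by identifier, scaffold and position.

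The first question was whether libraries of a cultivar resembled each other more than libraries of other cultivars. The mean distance on the log2(CPM + 1) scale was 122.8 between cultivars and 107.1 within them, a difference of 15.67 (exact one-sided permutation p = 0.014 over 280 assignments, with 0.0036 the smallest possible). The Niue libraries were the closest set, at a mean distance of 83.35, against 125.5 within Palau 10 and 112.5 within Sam-07. For 7 of the 9 libraries the nearest library was of the same cultivar. Palau 10 replicate 3 lay 152.2 and 156.3 from the other Palau 10 libraries, which were 68 apart, and its nearest library was Sam-07 replicate 3. In Palau 10 replicate 3, 913 of 13712 gene models with a mean of at least 5 CPM in the cultivar lay at least 4-fold from both other libraries, against 65 in replicate 1 and 51 in replicate 2. Sam-07 replicate 2 was nearest to Niue replicate 3, and 333 of 13408 gene models lay at least 4-fold from both other Sam-07 libraries there. Of 24 gene models present at 1 CPM or more in Sam-07 replicates 1 and 3 and without a fragment in Niue and Palau 10, 9 had no fragment in Sam-07 replicate 2, the deepest library. The share of such gene models with a fragment was thus 62.5% there, against 96% to 100% in each of the other 8 libraries. The grouping by cultivar missed the threshold without Niue replicate 2 (difference 11.66, p = 0.1, exact), Niue replicate 3 (8.087, p = 0.16), Niue replicate 4 (9.878, p = 0.15) or Sam-07 replicate 1 (14.59, p = 0.054). With log2(CPM + 5) the difference was 7.983 (exact permutation p = 0.061).

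**Figure D1:**
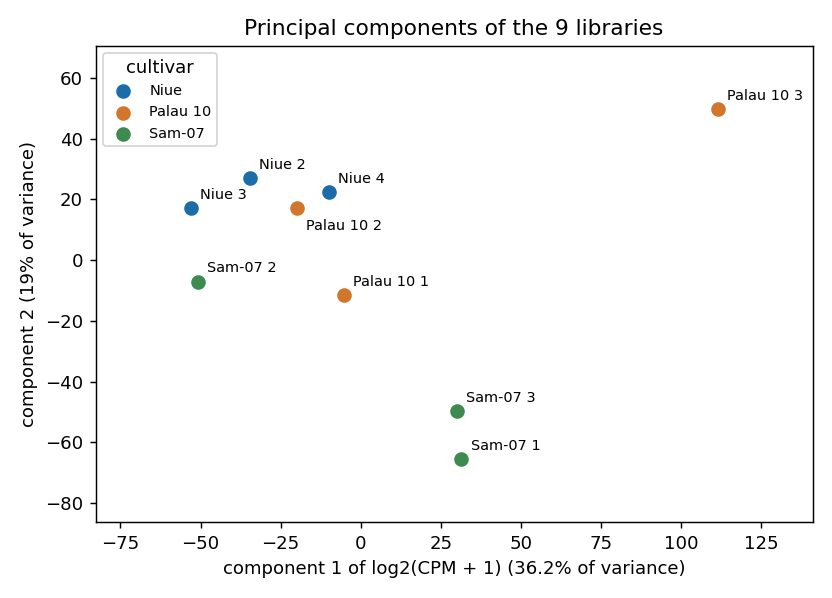
Principal components of log2(CPM + 1) for the 9 libraries, with component 1 (36.2% of the variance) on the horizontal axis, component 2 (19%) on the vertical axis and 1 point per library coloured by cultivar. Palau 10 replicate 3 stands apart on component 1, and Sam-07 replicates 1 and 3 lie apart from Sam-07 replicate 2.

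Between Palau 10 and Niue, the clearest differences were gene models expressed in 1 cultivar and not detected in the other. At 1 CPM or more in all 3 Niue libraries and without a fragment in Palau 10 were 70 called gene models, 20.5% of the calls. Of these, 27 were expressed in Sam-07 as well, 23 were not detected there and 20 lay between. In the opposite direction, 28 called gene models were expressed in Palau 10 and not detected in Niue. Taro_017633, with 10 exons on the plus strand of TARO_scaffold_000809 from 168425 to 177066, had 86.2 ± 17.0 CPM in Niue (SD, n = 3) and no fragment in Palau 10, at least 1324-fold lower there. Taro_033805, with 3 exons on TARO_scaffold_002612 from 71016 to 74152 (plus strand), had 67.65 ± 29.99 CPM in Niue and was at least 1039-fold lower in Palau 10. In the other direction, Taro_026615 (TARO_scaffold_001614, 244770 to 246278, plus strand, 6 exons) had 49.9 ± 6.37 CPM in Palau 10 and no fragment in Niue, at least 437.2-fold higher in Palau 10. Taro_054637 (TARO_scaffold_011275, 3490 to 6823, plus strand, 3 exons) had 28.0 ± 11.2 CPM in Palau 10, at least 244.8-fold higher than in Niue, and it had no fragment in Sam-07 either. Their adjusted p-values in edgeR's quasi-likelihood test were 0.00057 for Taro_017633, 0.0011 for Taro_033805 and Taro_026615, and 0.0088 for Taro_054637. The fitted log2 fold changes were -13.06 (SE 0.58), -12.71 (SE 0.81), 12.27 (SE 0.76) and 11.43 (SE 0.9) in the same order. Each of these gene models had no fragment in the lower cultivar, so these SEs do not measure how closely the folds are known. In all, 341 of 18865 tested gene models differed, 118 higher and 223 lower in Palau 10. The median size of a called change was 5.25 on the log2 scale as fitted, and 4.4 with the 118 gene models that had no fragment in the lower cultivar set at their bound. The count fell to 193, 163 or 156 without Niue replicate 2, 3 or 4, and to 190 or 183 without Palau 10 replicate 1 or 2. Without Palau 10 replicate 3 it rose to 423 (188 higher, 235 lower), with 284 of the 341 kept. It was 717 with DESeq2 (317 higher, 400 lower) and 90 when only gene models with at least 10 CPM in 3 libraries were tested. With the replicate number as a block the count was 1, and each gene model named here lost its call (edgeR's quasi-likelihood test, adjusted p 0.072 to 0.14). Niue replicate 4 has no same-numbered library in another cultivar, so the block took it out of this comparison.

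Between Sam-07 and Niue, 43 called gene models were expressed in Niue and not detected in Sam-07, and 25 were expressed in Sam-07 and not detected in Niue. Of the 43, 20 were not detected in Palau 10 either, and 11 were expressed there. Taro_046462 (TARO_scaffold_005727, 11654 to 16900, minus strand, 10 exons) had 170.2 ± 10.2 CPM in Sam-07 (SD, n = 3) and 4 fragments over the Niue libraries, a ratio of pooled fragments of 1097 (95% counting interval 428.3 to 4028), with 0.197 ± 0.0714 CPM in Palau 10. All 4 of these fragments were in Niue replicate 2, and without that library the fitted log2 fold change was 13.98. Niue then had no fragment of Taro_046462, so this value does not measure the fold. Taro_029108 (TARO_scaffold_001917, 113136 to 121881, minus strand, 3 exons) had 31.6 ± 7.72 CPM in Sam-07 and no fragment in Niue, at least 276.5-fold higher in Sam-07. From first to last exon, introns included, Taro_029108 overlaps a gene model on the opposite strand. Whether they share exon bases was not checked, and fragments on any such bases were not counted. Strand was not used, so RNA of the opposite strand on the exon bases of Taro_029108 alone would count for it. Taro_019470 (TARO_scaffold_000940, 2794 to 6192, plus strand, 7 exons) had 58.6 ± 13.7 CPM in Niue and was at least 760.9-fold lower in Sam-07. Taro_043727 (TARO_scaffold_004791, 84010 to 89849, plus strand, 10 exons) had 21.7 ± 2.34 CPM in Niue, at least 281.9-fold lower in Sam-07, and 0.470 ± 0.311 CPM in Palau 10. Adjusted p-values from edgeR's quasi-likelihood test were 0.00024 for Taro_046462, 0.0015 for Taro_029108, 0.0038 for Taro_019470 and 0.0023 for Taro_043727. The fitted log2 fold changes were 10.14 (SE 0.59), 11.61 (SE 0.7), -12.5 (SE 1.04) and -11.07 (SE 0.81) in the same order. Apart from Taro_046462, these gene models had no fragment in the lower cultivar, and their SEs do not measure how closely the folds are known. In all, 230 gene models differed, 87 higher and 143 lower in Sam-07. The median called change was 5.49 on the log2 scale as fitted, and 4.75 with the 74 gene models without a fragment in the lower cultivar at their bound. The count fell to 101, 109 or 91 without Niue replicate 2, 3 or 4, and to 119 or 122 without Sam-07 replicate 1 or 3. Without Sam-07 replicate 2 it was 220 (100 higher, 120 lower), of which 148 were among the 230. It rose to 341 (121 higher, 220 lower) without Palau 10 replicate 3, a library outside the pair. It was 582 with DESeq2, 66 under the 10 CPM filter and 9 with the replicate number as a block, which again took out Niue replicate 4.

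Between Sam-07 and Palau 10, 46 called gene models were expressed in Sam-07 and not detected in Palau 10, and 29 were expressed in Palau 10 and not detected in Sam-07. Of the 46, 27 were expressed in Niue as well. Taro_017633, without a fragment in Palau 10, had 57.9 ± 17.8 CPM in Sam-07 (SD, n = 3), at least 888.4-fold higher than in Palau 10. Taro_041985 (TARO_scaffold_004295, 98768 to 104254, plus strand, 7 exons) had 49.1 ± 16.7 CPM in Sam-07, at least 753.2-fold higher than in Palau 10, and 64.8 ± 18.1 CPM in Niue. Taro_019470 had 67.5 ± 37.9 CPM in Palau 10 and no fragment in Sam-07, at least 875.6-fold lower in Sam-07. Taro_054637 was at least 362.8-fold lower in Sam-07 than in Palau 10. In edgeR's quasi-likelihood test the adjusted p-values were 0.00035 for Taro_017633, 0.00056 for Taro_041985, 0.0021 for Taro_019470 and 0.0077 for Taro_054637. The corresponding fitted log2 fold changes were 12.48 (SE 0.58), 12.24 (SE 0.68), -12.7 (SE 1.03) and -11.43 (SE 0.85). As each had no fragment in the lower cultivar, the SEs do not measure how closely the folds are known. In all, 327 gene models differed, 160 higher and 167 lower in Sam-07. The median called change was 5.42 on the log2 scale as fitted, and 4.17 with 107 gene models at their bound. The count fell to 197 without Niue replicate 4, to 172 or 171 without Palau 10 replicate 1 or 2, and to 174, 198 or 156 without Sam-07 replicate 1, 2 or 3, with 171 of the 327 kept without replicate 2. Without Palau 10 replicate 3 it was 402 (164 higher, 238 lower). It was 739 with DESeq2, 82 under the 10 CPM filter, 70 with the replicate number as a block and 210 with only the 6 libraries of the pair in the fit.

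**Figure D2:**
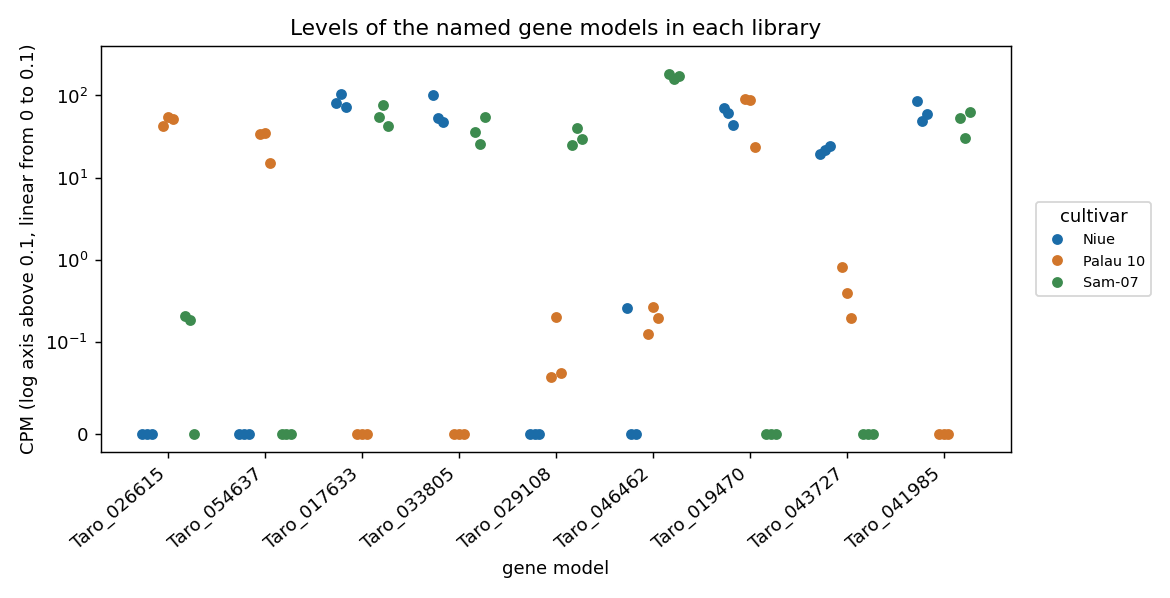
CPM of the 9 named gene models (vertical axis, logarithmic above 0.1 and linear below), with 1 point per library coloured by cultivar. Taro_017633 is at 0 in the 3 Palau 10 libraries and at 42.25 CPM or more in the other 6 libraries.

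Over the 3 cultivars together, 153 called gene models were expressed in 1 cultivar and not detected in another. Expressed in a single cultivar and not detected in the other 2 were 23 gene models for Niue, 11 for Palau 10 and 13 for Sam-07. Not detected in a single cultivar and expressed in the other 2 were 11 gene models for Niue, 27 for Palau 10 and 11 for Sam-07. Their levels were low, with a median between 3.48 and 4.78 CPM in the expressing cultivar across the 6 directions. Requiring 5 CPM in place of 1 CPM left 52 gene models, and leaving out Niue replicate 4 left 102. By comparison, 14916 gene models were at 1 CPM or more in all 9 libraries. The test of any difference among the 3 cultivars called 513 gene models, 2.72% of those tested (edgeR quasi-likelihood F-test, adjusted p under 0.05). It called 337, 320 or 273 without Niue replicate 2, 3 or 4, 318 or 323 without Palau 10 replicate 1 or 2, and 341 or 331 without Sam-07 replicate 1 or 3. DESeq2 called 1133, the 10 CPM filter left 127 and the replicate number as a block left 25.

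**Figure D3:**
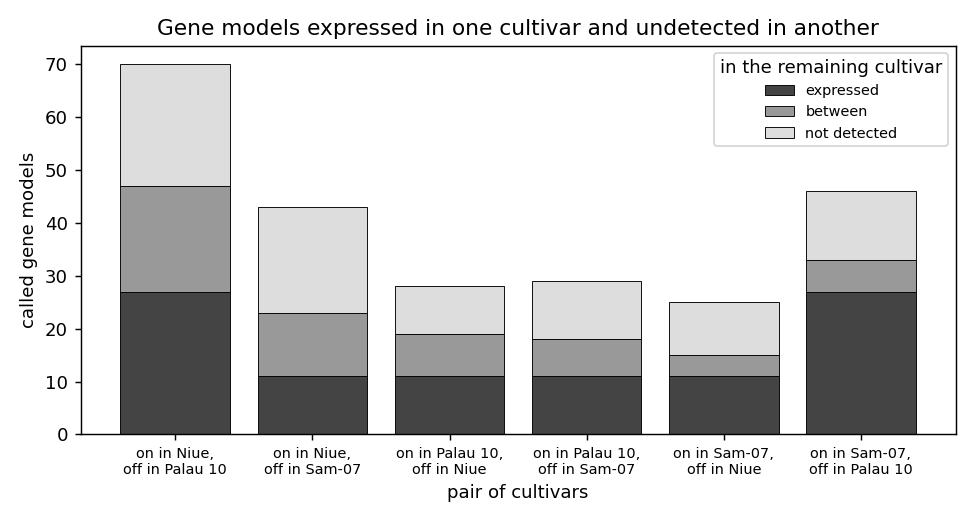
Number of called gene models (vertical axis) at 1 CPM or more in all 3 libraries of 1 cultivar (on) and without a fragment in another (off), for each ordered pair of cultivars, with bars divided by the state of the remaining cultivar. The highest bar is that of the 70 gene models on in Niue and off in Palau 10.

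Palau 10 and Sam-07 were also compared through their differences from Niue. Called in both comparisons with the same sign were 113 gene models, 42 higher and 71 lower than in Niue, and 2 were called with opposite signs. Independent lists of these sizes would share 0.54 higher and 1.69 lower gene models. In 20 simulated runs both unchanged groups were set against 1 set of simulated Niue libraries, and no gene model was called in both with the same sign. All 9 libraries were drawn anew in each run, so traits of the real Niue libraries were not in them. These runs held no effects, so their 0 does not show how many gene models the shared Niue libraries would add to lists of these sizes. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.56, against 0.52 in the simulated runs, and a covariance of 0.81 against 0.18, a difference of 0.63. The 3 Niue libraries cannot be divided into sets of 2, so part of the overlap may come from the shared controls. The overlap was 46, 42 or 36 without Niue replicate 2, 3 or 4, 75 or 72 without Palau 10 replicate 1 or 2, and 64 or 63 without Sam-07 replicate 1 or 3. It was 213 with DESeq2 and 28 under the 10 CPM filter.

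Gene structure was compared between called and other gene models for 89 classes of exon number, summed exon length and scaffold, of which 6 passed an adjusted p of 0.05 in Fisher's exact test. In the shortest length class (up to 945 bp, 4731 of the tested gene models), 4.19% were called among the 3 cultivars, against 2.23% of the rest (odds ratio 1.92, adjusted p = 7.74e-10). In the longest class (over 2208 bp) 1.7% were called, against 3.06% of the rest. Gene models with 1 exon were called less often (1.45% against 2.86%), as were those with 6 or more exons (2.21% against 3.07%), and those with 3 to 5 exons more often (3.45% against 2.31%). On TARO_scaffold_000154, 6 of 37 tested gene models were called (odds ratio 6.99, adjusted p = 0.00655), and without Niue replicate 2 the odds ratio was 3.21 (Fisher's exact p = 0.14), without Palau 10 replicate 3 it was 4.38, with library size only 4.36 and with DESeq2 3.67, and under the 10 CPM filter none was called. The test treats gene models as independent, although neighbours can vary together. With no filter on low counts the odds ratio of the shortest class was 1.07 (Fisher's exact p = 0.42), and without Palau 10 replicate 1 or Sam-07 replicate 2 only 1 or 3 classes passed. Under the 10 CPM filter 0 classes passed.

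A set of 5 abundant gene models, singled out after their values were seen, varied together between libraries. The set held Taro_025253 and Taro_025252, which lie 47022 to 51707 on the minus strand of TARO_scaffold_001466, with Taro_000496, Taro_027264 and Taro_036193 on other scaffolds. Together they took 0.9006%, 12.54% and 26.31% of the fragments in Niue replicates 2, 3 and 4. The shares were 1.857%, 0.7519% and 2.589% in Palau 10 replicates 1, 2 and 3, and 7.104%, 0.3511% and 6.408% in Sam-07 replicates 1, 2 and 3. No difference in this share between the cultivars was detected beyond the spread between libraries (exact permutation p = 0.5 on the log10 share over 280 assignments). Taro_039095, on TARO_scaffold_003588, took a mean of 2.153% of the fragments and was not called among the cultivars (edgeR adjusted p = 0.85).

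**Figure D4:**
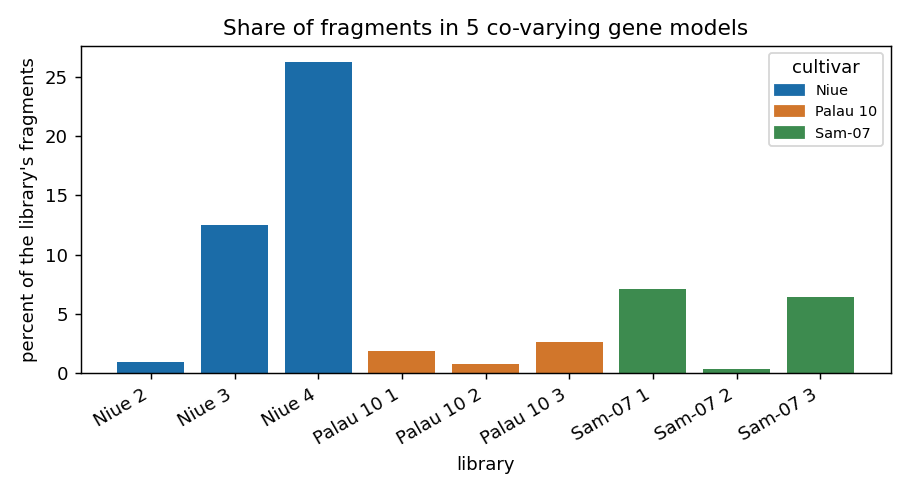
Percent of each library's fragments (vertical axis) in the 5 gene models that varied together, with 1 bar per library coloured by cultivar. The share runs from 0.3511% in Sam-07 replicate 2 to 26.31% in Niue replicate 4.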

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

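Thinning, the removal of the 5 abundant gene models, leave-one-out for the on/off gene models, the similarity and the structural classes, and the block (with DESeq2 for the on/off gene models) for the on/off gene models and the overlap were chosen after seeing the data. The planned gene list tests were not run because no gene model has a name, nor was the summing to parent genes. RLE factors, library size only, no filter, robust estimation and a 2-fold threshold left the 3 pairwise counts within 1.5 times. Library size only moved the median log2 fold change of all gene models between Palau 10 and Niue to 0.16 (from 0.023), and directions are relative to TMM. DESeq2 called 717 gene models between Palau 10 and Niue, 582 between Sam-07 and Niue, 739 between Sam-07 and Palau 10 and 1133 among the 3 cultivars, and the overlap rose to 213. The 10 CPM filter, which tests fewer gene models, gave 90, 66, 82 and 127 in the same order, with an overlap of 28 and 0 structural classes, and odds ratios of 0 for TARO_scaffold_000154 and 1.96 for the shortest length class. Between Sam-07 and Palau 10, thinning gave 206 and the 6 libraries of the pair alone 210. With 5 CPM for presence, 52 on/off gene models were left. With log2(CPM + 5) the difference in distance was 7.983 (exact permutation p = 0.061). Beyond the number of gene models tested or samples used, the cause was not tested.

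Leaving out 1 library gave 156 to 423 calls between Palau 10 and Niue, 91 to 341 between Sam-07 and Niue, 156 to 402 between Sam-07 and Palau 10 and 273 to 662 among the 3 cultivars. It gave an overlap of 36 to 139, 102 to 160 on/off gene models, a difference in distance of 8.087 to 22.58 and 1 to 5 structural classes. The highest counts of calls, of the overlap and of on/off gene models all came without Palau 10 replicate 3.

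Whether the replicate numbers pair the samples was not settled. Over 7 same-numbered pairs the correlation of deviations ran from -0.48 to 0.42, with 3 over 0.1. No differently numbered pairs were set against them. The abundant gene models that varied together had their lowest share in replicate 2 of Niue (0.9006%), Palau 10 (0.7519%) and Sam-07 (0.3511%). A batch that follows the replicate number therefore remains open. With the replicate block, which costs degrees of freedom, the counts were 1, 9, 70 and 25. The overlap was 1, the on/off gene models 17 and the odds ratios 0 for TARO_scaffold_000154 and 1.68 for the shortest length class (Fisher's exact p = 0.25). Only Niue has a replicate 4, so the block took that library out and left Niue replicates 2 and 3 for its comparisons. The low counts of 1 and 9 against Niue can come from this loss as well, so they do not show a batch. Of 228 refits of named gene models over all alternatives, 221 kept direction and call, 7 lost the call, all under the block, and 0 reversed. The block took the call from every gene model named between Palau 10 and Niue (edgeR's quasi-likelihood test, adjusted p 0.072 to 0.14). It also took the call from Taro_019470 and Taro_043727 between Sam-07 and Niue and from Taro_054637 between Sam-07 and Palau 10. The named gene models were chosen for the largest changes in these data.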

Other observations

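Of the tests in this part, the splits of the samples and the strand test over all 3 comparisons were written before their results were seen. The tests on the 5 abundant gene models, on Palau 10 replicate 3 and Sam-07 replicate 2 and on missing segments, and the strand test for Palau 10 and Niue alone, were chosen after the values were seen.

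Gene models called in the same direction lay next to each other on scaffolds more often than shuffled calls. Among 13005 pairs of neighbouring, non-overlapping tested gene models, 19 were called in the same direction between Palau 10 and Niue, against 2.33 with shuffled calls. There were 16 against 1.01 between Sam-07 and Niue and 16 against 1.93 between Sam-07 and Palau 10 (permutation p = 0.0001 in each, the smallest that 10000 shuffles give). The comparisons share cultivars, and these counts hold 34 distinct pairs, 17 of them in more than 1 comparison. Pairs called in opposite directions numbered 3, 2 and 2, against 1.92, 0.92 and 1.95 with shuffled calls. On TARO_scaffold_002216 from 174340 to 199626, 3 consecutive tested gene models were lower in Sam-07 than in Niue and in Palau 10, and so were 3 on TARO_scaffold_008377 from 4838 to 18810.

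A gene annotated as 2 models on a strand would give such pairs on the same strand. Between Palau 10 and Niue, 9 of the pairs lay on opposite strands, against 0.98 with shuffled calls (permutation p = 0.0001), which that explanation does not give. Another 10 lay on the same strand, against 1.34 (permutation p = 0.0001), and divided gene models remain open for these. Between Sam-07 and Niue 2 lay on opposite strands against 0.41 (permutation p = 0.064), and between Sam-07 and Palau 10 2 against 0.82 (permutation p = 0.2). On the same strand lay 14 in each, against 0.57 and 1.12, so divided gene models remain open there as well. Pairs at least 5000 bp apart numbered 14 between Palau 10 and Niue, 11 between Sam-07 and Niue and 9 between Sam-07 and Palau 10. Shuffled calls gave 1.64, 0.72 and 1.35 in the same order. No limit was set for how far apart divided gene models can lie, so the distance does not decide this. In 13 of 34 distinct pairs (38.2%) a member had a mean of 1 CPM or more in the lower cultivar of a comparison. For that comparison, this argues against a segment with both members that is wholly missing from the cultivar. Only 6 of the 34 had no fragment of either member there, and 18 had fragments of both. A pair counted where the state held in any comparison that called it. The 38.2% fell between the limits set for the test, so long missing segments remain open for the pairs as a set. Sequence differences that keep fragments from mapping to the reference may account for pairs too, but need genome sequence of the cultivars, which was not used here.

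The 5 abundant gene models ranged 29.2-fold in summed share within Niue, which argues against cultivar as the whole cause. The highest and lowest cultivar means were 7.65-fold apart. Means of 3 libraries vary less than single libraries, so the smaller fold between means adds nothing to this. With the models picked on Palau 10 and Sam-07 libraries alone, their log2 ratio to Taro_025253 had a median SD of 0.18 over the 3 Niue libraries, where Taro_025253 itself had an SD of 2.57. For most of the models, 1 source of RNA that enters the libraries in fixed proportions would give this, although the same models had been seen over all 9 libraries. Over all 9, the SD of the log2 ratio was 0.09 for Taro_000496, 0.14 for Taro_025252 and 0.17 for Taro_036193. It was 0.46 for Taro_027264, whose proportion was less fixed. The models were picked by a correlation of at least 0.98 with Taro_025253, which favours steady ratios. That their own fragments drive the calls between cultivars is argued against, since without them at least 93.9% of the calls were kept in each comparison. TMM factors limit the weight of a few abundant gene models in both fits, and other gene models that vary with them were not removed. Whether the source of this variation also moves the calls through other gene models was therefore not tested. No name shows what they encode, and differences in leaf state remain untested.

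Palau 10 replicate 3 and Sam-07 replicate 2 stood apart from their cultivars, in 913 and 333 gene models. For Palau 10 replicate 3, a wrong label is argued against by 100% of the 19 gene models seen only in the other Palau 10 libraries having fragments there, RNA of another cultivar by a median level of 0% over 29 gene models that replicates 1 and 2 lack, and depth by a total of 95.7% of their mean. In Sam-07 replicate 2, 62.5% of the 24 gene models seen only in the other Sam-07 libraries had a fragment, against 96% to 100% in each of the other 8 libraries, and Niue and Palau 10 have none of these fragments, which argues against a Niue or Palau 10 library under its label. The 37.5% without a fragment leave open that it came from another genotype than the other Sam-07 libraries, and without it 148 of the 230 calls against Niue and 171 of the 327 against Palau 10 were kept, among 220 and 198 calls. For both libraries a difference in the state of the plant or leaf, or in handling, may remain and was not tested.

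For the count among the 3 cultivars, 100 of the 280 splits of the 9 libraries into groups of 3 were run. Of these, 1, the real one, gave 513 gene models and the highest other gave 86, which argues against a chance split. The other splits mix cultivars within groups, which widens the spread and can lower their counts. A difference in plants or handling that follows cultivar was not tested by the splits. For the pairs of cultivars the 10 splits of 6 libraries are too few for a share under 0.05. The real split (1 of 10 in each) gave 341 between Palau 10 and Niue, 230 between Sam-07 and Niue and 327 between Sam-07 and Palau 10, and the highest other gave 0, 0 and 13.

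In Sam-07 replicate 2, the 9 gene models without a fragment had 12 to 35 fragments in replicate 1 and 10 to 50 in replicate 3, while the other 15 of the 24 had a fragment in all 3 Sam-07 libraries.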
